A study of Mus musculus with 4 samples.

How the data were processed

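The series holds 4 samples of the mouse osteosarcoma line K7M2 grown in serum-containing medium, 1 over-expressing GFP and 3 over-expressing ezrinT567A-GFP. Per the labels' protocols, total RNA was extracted with a column kit and turned into biotinylated cRNA by the one-cycle labelling assay of Affymetrix for a one-colour array. The deposited values are log2 expression per probe set, summarised and normalized with RMA per the submitters' processing notes, and they ran from 1.18 to 13.7 with no missing value. That they are on the log2 scale was read from this range and from the array medians. The software that ran RMA, and its version, are not given in the sources used here. RMA forces the arrays to nearly the same distribution, so a change in total RNA per cell would not be seen, and values near the bottom of the scale are background rather than expression.

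Probe sets were named from the platform annotation table. Of 45101 probe sets 34958 had 1 gene symbol, 932 had several and 9211 were not listed. Of 64 control probe sets, 13 had a gene symbol and 51 were not listed. Gene IDs were matched to a gene table of assembly GRCm38.p6, which found 34754 of them and changed 0 symbols. That table was also used for chromosomes and for which genes neighbour each other, and no coordinate was taken from it. Control probe sets and those with several or no listed genes were left out of the tests. Each of the 18193 genes was represented by the probe set with the highest mean log2 over the 4 arrays, and 9012 genes had more than 1 probe set, whose range of differences is given for named genes where probe sets differ in sign, and for some others where they differ in size. No filter on dim genes was used in the tests of genes and lists, while the values by chromosome used only genes whose mean level lay above the median of all genes. Array-specific signal over background was not analysed here.

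Groups were taken from the over-expression label, and the comparison was ezrinT567A-GFP (3 arrays) against GFP (1 array). Values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend) and adjusted over all genes after Benjamini and Hochberg, with a threshold of 0.05. The fit had 2 residual degrees of freedom, all from the ezrinT567A-GFP arrays, and a prior worth 2.23. SE is the moderated standard error, and all tests were two-sided. No batch label was given, so no batch could be set against the groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

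There were 27 gene lists, fixed before the data were examined, covering ezrin's family and partners, actin targets, adhesion, proteases, matrix, metabolism, growth, stress, interferon and cytokine responses, osteoblasts, and markers of other cell types. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation and with fry. A list's median was also set against 10000 random lists matched on mean expression. On that scale the interferon, cholesterol, fatty acid and ATF4 lists lay at percentile 100, cell cycle and epithelial markers at 0, collagens at 0.90 and the unfolded protein response at 11.9.

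The genes named in the text were set by a rule fixed in advance: Ezr, the 12 largest rises and 12 largest falls among genes past the threshold, or, because 0 genes passed, the 12 genes per direction with the largest moderated t that had all 3 arrays on one side of GFP, a level above the median of all genes and no clone or predicted name. Up to 4 members of each list with the smallest p were added. Genes named outside this rule are said to have been chosen after their values were seen.

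The scripts were tested on simulated data before use. In 20 simulations of this comparison over 18193 genes with 200 changed genes, limma recovered 67.05% of 4-fold and 13.95% of 2-fold changes with 1.6 false calls on average, when genes of a list were uncorrelated, and 66.45% and 12.6% when they were correlated at 0.2. Camera with the preset correlation called 0.577% of unchanged lists without correlation and 20% with it. The simulated arrays held no genes with tied values, and the simulated GFP array varied only like the others. These shares may therefore differ from those of the real arrays.

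Alternatives tried were quantile normalization or median centring of the arrays, the mean of a gene's probe sets, leaving out probe sets of the _s_at, _x_at and _a_at kinds, leaving out dim genes, eBayes without trend or with a robust prior, treat, other thresholds, and leaving out each replicate. A spike-in covariate and the removal of genes with tied values were added after seeing the data. Explanations weighed in the closing section were tested with 35 keratinocyte genes, 32 of them measured, written down after the keratins had been seen, with the Xist probe sets, and with running windows of 25 neighbouring genes.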

Results

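Gene expression was measured on 4 one-colour arrays of K7M2, a mouse osteosarcoma cell line that metastasises readily. The cells over-expressed either GFP alone (1 array) or ezrinT567A-GFP (3 arrays, replicates 1 to 3). Ezrin links membrane proteins to the actin cortex, and T567A names an ezrin whose regulatory C-terminal threonine is replaced by alanine, which cannot be phosphorylated. The arrays held 45101 probe sets, summarised here as 18193 named genes, with array medians between 3.85 and 3.89 on the log2 scale. The number of arrays limits the precision, and nothing in the labels says that the 3 replicates were separate cultures or clones, so the p-values measure only the spread between these arrays. The single GFP array was assumed to vary like the others, and an exact permutation of 4 arrays cannot go below p = 0.25. All differences below are ezrinT567A-GFP mean minus GFP, on the log2 scale.

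The first question was whether the over-expressed gene itself could be seen. Ezr, measured by the brighter of its probe sets, was 8.90 in GFP and 8.91 ± 0.09 (SD, n = 3) in ezrinT567A-GFP, a difference of 0.01 (SE 0.12, limma adjusted p = 0.977). A further Ezr probe set gave 8.63 in GFP and 8.96 ± 0.18 (SD, n = 3), a difference of 0.33 (SE 0.18). The first difference lay within the spread between arrays. The second exceeded its SD and SE, with all 3 arrays above GFP, but did not pass limma's test over all probe sets (adjusted p = 0.531). A probe set outside the sequence of the transgene, or a transgene of another species, would check nothing, so these values neither bear out nor contradict the labels.

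The ezrinT567A-GFP arrays resembled each other more than they resembled the GFP array. Across genes, which are not independent replicates, Pearson's r was 0.993 between replicates 1 and 2, 0.995 between 1 and 3 and 0.995 between 2 and 3, against 0.990, 0.987 and 0.990 between GFP and replicates 1, 2 and 3. The median gene had an SD of 0.13 over the 3 ezrinT567A-GFP arrays. Pairs of these arrays differed at least 2-fold at 153, 81 and 44 genes, and each of them differed from GFP at 353, 469 and 343 genes. The control probe sets moved too: hybridization spike-ins averaged 9.32 in GFP and 10.1, 11.1 and 10.4 in replicates 1, 2 and 3, and 18S rRNA averaged 9.09 in GFP and 7.65, 11.3 and 7.76. Among genes with a mean level above the median of all genes, those of chromosome 1 had a median of -0.34 over 510 genes, below 0 in each ezrinT567A-GFP array, and those of chromosome 8 a median of 0.24 over 516 genes.

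The main comparison asked which genes differ between cells with ezrinT567A-GFP and cells with GFP alone. Among the genes with the largest moderated t, the largest differences lay on the lower side. Amhr2, the receptor for anti-Müllerian hormone, was lower by -3.54 (SE 0.18), which is 11.6-fold. Hsd11b1, the enzyme that regenerates active glucocorticoid, was lower by -3.36 (SE 0.14), from 9.31 in GFP to 5.95 ± 0.10 (SD, n = 3), and Ppbp, a chemokine best known from platelets, by -3.27 (SE 0.15). On the higher side stood Srpx2, a secreted sushi-repeat protein, at 2.38 (SE 0.12) from a dim 3.21 in GFP, and Oas3, an interferon-induced antiviral enzyme, at 2.05 (SE 0.17).

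Among the other genes of that ranking, Scd2 (1.34), Mvd (1.67), Cyp51 (1.90) and Msmo1 (1.81), all enzymes of fatty acid desaturation or sterol synthesis, were higher. Also higher were the lysosomal galactosidase Gla (1.93), the fucosidase Fuca2 (1.46), the secreted protease Adamts1 (from 5.61 to 7.11), the mitochondrial micropeptide gene Mtln (1.44), Mfsd6 (1.91) and Renbp (1.41). Lower were the basal epithelial keratins Krt17 (-2.54) and Krt5 (-2.05), the desmosomal protein gene Perp (-2.79), the laminin-binding integrin Itga6 (-2.47), the collagenase Mmp13 (-2.30), the receptor-associated Ramp1 (-1.72), the heparan endosulfatase Sulf2 (-1.39), the metalloprotease Adam12 (-1.20) and Flacc1 (-1.18). The rule that chose these 24 genes required all 3 ezrinT567A-GFP arrays to lie on one side of GFP. The ezrinT567A-GFP levels of Perp (2.27) and Krt17 (2.85) lay near the lower quartile of the arrays (2.55 to 2.62), where values are not shown to be above background, so the size of these differences is uncertain. Probe sets of one gene disagreed for several of them, among them Gla (0.23 to 1.93), Fuca2 (-0.04 to 1.46), Msmo1 (0.33 to 1.81), Cyp51 (0.56 to 1.90), Krt17 (-2.54 to -0.20), Ramp1 (-1.72 to 0.09), Flacc1 (-1.18 to 0.10) and Sulf2 (-1.39 to 0.28).

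**Figure D1:**
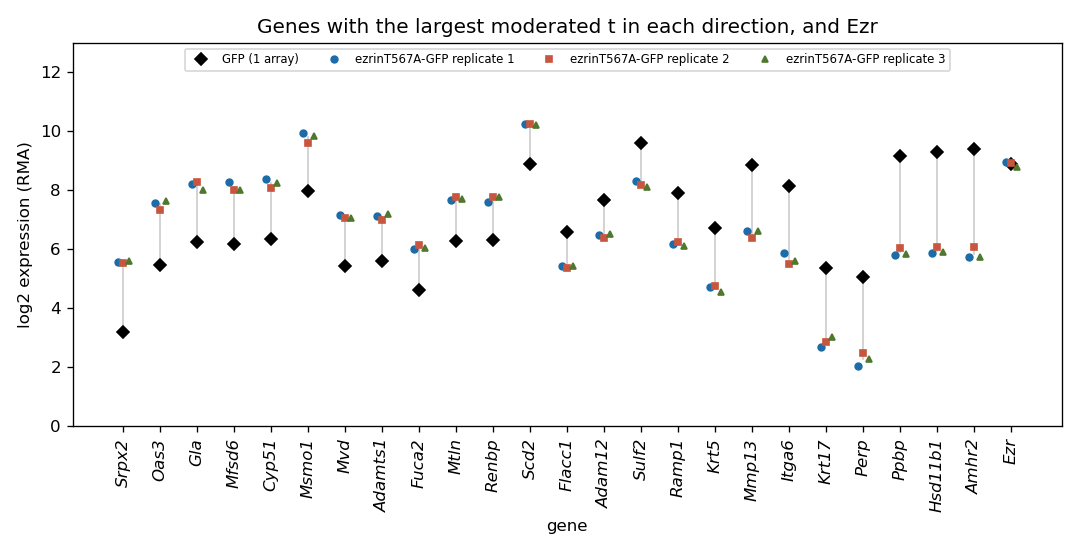
Log2 expression (y axis, RMA) of the 24 genes of the naming rule and of Ezr (x axis). Values are shown for the single GFP array (diamond) and for each of the 3 ezrinT567A-GFP arrays. The 24 genes had the largest moderated t among genes past the rule's filters on level, name and side of GFP. The 3 ezrinT567A-GFP arrays sit close together and apart from GFP for each of the 24 genes, as the rule that chose them required, and Ezr differed by 0.01.

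None of these single genes passed the test over all genes. With limma, 0 of 18193 genes had an adjusted p under 0.05, with or without a 2-fold minimum. The lowest adjusted p was 0.0805, shared by 6 genes, among them Hsd11b1, Ppbp, Amhr2 and Srpx2, and the 24 genes above had adjusted p between 0.0805 and 0.187. At an unadjusted p under 0.05 there were 2540 genes (1357 higher and 1183 lower), where chance gives 910. At least 2-fold apart were 177 genes above and 128 below GFP, of which 176 and 126 kept their side in all 3 arrays. Setting each ezrinT567A-GFP array in turn against the remaining 3 arrays, GFP among them, gave 72, 98 and 30 genes at least 2-fold apart instead of 305. At an unadjusted p under 0.05 the grouping with replicate 2 as the single array also exceeded 910 genes, while those with replicates 1 and 3 did not. An excess over 910 therefore does not by itself show an effect of ezrinT567A-GFP. The count of 0 depended on the processing: limma called 34 genes after quantile normalization, 30 after centring the arrays, 9 with a robust prior, 6 with the mean of a gene's probe sets, 3 without the dimmer genes, and 28 when 97 genes with tied values on all 3 ezrinT567A-GFP arrays were left out, a choice made after seeing the data, while treat called 0.

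Gene lists fixed before the data were examined showed where the differences gathered. Camera at the preset correlation also called lists with an ezrinT567A-GFP array as the single one. For replicate 1 these included fatty acid synthesis and ATF4, and for replicate 2 the interferon and cell cycle lists. The medians of replicate 2 against the remaining arrays, GFP among them, were 0.81 for interferon and -0.31 for the cell cycle. Because GFP was among the remaining arrays, its own difference fed these calls. For fatty acid synthesis, replicate 1 had the lowest median against GFP (0.47, against 0.50 and 0.52 in replicates 2 and 3). These groupings therefore cannot show whether a call was particular to the GFP array. The interferon response stood out most. Of 30 measured interferon-response genes 28 were higher in ezrinT567A-GFP, 21 of them at least 2-fold, and the median difference was 1.45, with array medians of 1.42 ± 0.23 (SD, n = 3). Usp18, which removes ISG15 from proteins, was higher by 2.43 (SE 0.24), the antiviral enzyme Rsad2 by 2.25 (SE 0.24), Ifit2, which binds foreign RNA, by 1.83 (SE 0.19) and Ifi35 by 1.48 (SE 0.17). Psmb8 (-0.14) and B2m (-0.04, probe sets -0.04 to 0.14) were the 2 members not higher. They belong to antigen presentation, as do Tap1 (0.57, probe sets 0.0044 to 0.57) and Psmb9 (0.33), which were higher in all 3 arrays. These genes were singled out after their values were seen. Of the 30 genes, 27 passed adjusted over the list alone and 0 over all genes. The list passed limma's camera (adjusted p = 3.78e-19), with adjusted p = 0.766 with an estimated correlation. Replicate 2, which had the highest spike-in and 18S signals, also had the highest interferon median (1.67, against 1.21 and 1.38), and with the spike-in level as a covariate, chosen after seeing the data, the median difference was 0.78 and the list still passed.

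By the probe set that stood for each gene, cholesterol synthesis was the only list whose measured members all lay on the same side of GFP. All 18 measured members were higher in all 3 arrays, 9 of them at least 2-fold, with a median of 1.03 and array medians of 0.97 ± 0.03 (SD, n = 3). Probe sets disagreed in sign for Fdft1 (-0.19 to 1.04), Sc5d (-0.35 to 0.34) and Hsd17b7 (-0.11 to 0.23), singled out after their values were seen. Mvd and Cyp51, enzymes of the mevalonate and post-squalene steps, led with Msmo1, and Lss, which closes the sterol rings, was higher by 1.06 (SE 0.12). The test passed 14 of these genes adjusted over the list alone and 0 over all genes. Camera gave adjusted p = 1.41e-13, and adjusted p = 0.377 with an estimated correlation, and this was the only list past the threshold with fry (adjusted p = 0.00047).

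Fatty acid synthesis moved alongside it, with 15 of 16 genes higher, 3 at least 2-fold, and a median of 0.47. Scd2 and Scd1 (0.94, SE 0.13), which desaturate stearate, Fads1, a polyunsaturated fatty acid desaturase (1.19, SE 0.19), and Acss2, which makes acetyl-CoA from acetate (1.54, SE 0.28), had the smallest p. Probe sets of Fads1 ranged from 0.26 to 1.19 and those of Acss2 from 0.11 to 1.54. In this list 10 genes passed adjusted over the list alone and 0 over all genes. Camera gave adjusted p = 6.06e-08, and adjusted p = 0.477 with an estimated correlation.

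The amino acid and ATF4 response was higher more modestly, in 21 of 22 genes, with a median of 0.37. Slc3a2, a subunit of amino acid exchangers, was higher by 0.53 (SE 0.14), the transaminase Gpt2 by 0.69 (SE 0.24), the transcription factor Atf5 by 1.18 (SE 0.42) and the stress-induced Sesn2 by 0.50 (SE 0.18). Adjusted over the list alone 0 genes passed, as over all genes, and 4 had an unadjusted p under 0.05. Camera gave adjusted p = 0.000925, and adjusted p = 0.888 with an estimated correlation. The array medians were uneven, at 0.66 in replicate 1, 0.26 in replicate 2 and 0.19 in replicate 3, and the median difference was 0.21 without replicate 1 and 0.58 without replicate 3, with the call kept both times. With the spike-in covariate it was 0.71, also with the call kept.

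Cell cycle genes were lower, 29 of 31 of them, with a median of -0.41 and array medians of -0.41 ± 0.07 (SD, n = 3). Tyms, which makes thymidylate, was lower by -1.10 (SE 0.15), the checkpoint kinase Chek1 by -0.74 (SE 0.12), the replicative helicase subunit Mcm6 by -0.80 (SE 0.13) and the mitotic kinase Cdk1 by -0.49 (SE 0.08). Probe sets disagreed for Tyms (-1.10 to 0.10) and Chek1 (-0.89 to 0.30). Adjusted over the list alone 6 genes passed, and over all genes 0. Camera gave adjusted p = 1.48e-12, and adjusted p = 0.766 with an estimated correlation, and with the spike-in covariate the median was -0.21 and the list still passed.

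Epithelial markers were lower in 9 of 12 genes, with a median of -0.33. The basal keratins Krt5 and Krt14 (-2.80, SE 0.43) were the 2 genes that passed adjusted over the list alone, and 0 passed over all genes. The adherens junction cadherin Cdh1 (-1.28, SE 0.36) and the tight junction gene Cldn4 (-0.65, SE 0.19) were lower from dim GFP levels of 4.21 and 3.75. A further Krt14 probe set gave 0.08, and the list median was -0.20 with the mean of a gene's probe sets and -0.54 with the spike-in covariate, with the call kept in both. Camera gave adjusted p = 0.00087, and adjusted p = 0.766 with an estimated correlation. Of 22 other keratinocyte genes, chosen after the keratins had been seen, 17 were lower and 5 higher, with a median of -0.30, and 0 passed limma's test over all genes, 6 of the 22 lying above the median level of all genes.

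Collagens and matrix genes were slightly lower, 18 of 27, with a median of -0.12. The fibrillar collagen Col5a1 (-0.53, SE 0.11, probe sets -0.53 to 0.07), the basement membrane collagen Col18a1 (-0.53, SE 0.12), Col6a2 (-0.48, SE 0.17) and the glycoprotein gene Tnc (-0.30, SE 0.12) had the smallest p. Chaperones and other genes of the unfolded protein response were lower in 16 of 22, with a median of -0.06 and a mean of -0.18. The disulfide isomerases Pdia3 (-0.45, SE 0.09) and Pdia4 (-0.70, SE 0.20), the secreted Manf (-0.54, SE 0.13) and the cochaperone Dnajc3 (-1.01, SE 0.26) led this list. Adjusted over the list alone 0 genes passed in either list, as over all genes, where 3 and 6 had an unadjusted p under 0.05. Camera gave adjusted p = 0.0265 for collagens and 0.0426 for the unfolded protein response, each with adjusted p = 0.789 with an estimated correlation. The collagen call ended without replicate 2 (median -0.06, adjusted p = 0.182) or 3 (median -0.11, adjusted p = 0.0823), with the mean of probe sets (median -0.03) and with the spike-in covariate (median -0.0023, adjusted p = 0.971, camera pointing up). The unfolded protein response call ended without replicate 1 (median -0.11, adjusted p = 0.0559), 2 (median -0.13, adjusted p = 0.182) or 3 (median -0.08, adjusted p = 0.0523), although these medians lay further from 0 than that of all 3 arrays, and also without dim genes, without a mean trend and with the spike-in covariate (median -0.03, adjusted p = 0.925), while with the _at kind of probe sets alone its median was -0.24 and the call was kept.

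**Figure D2:**
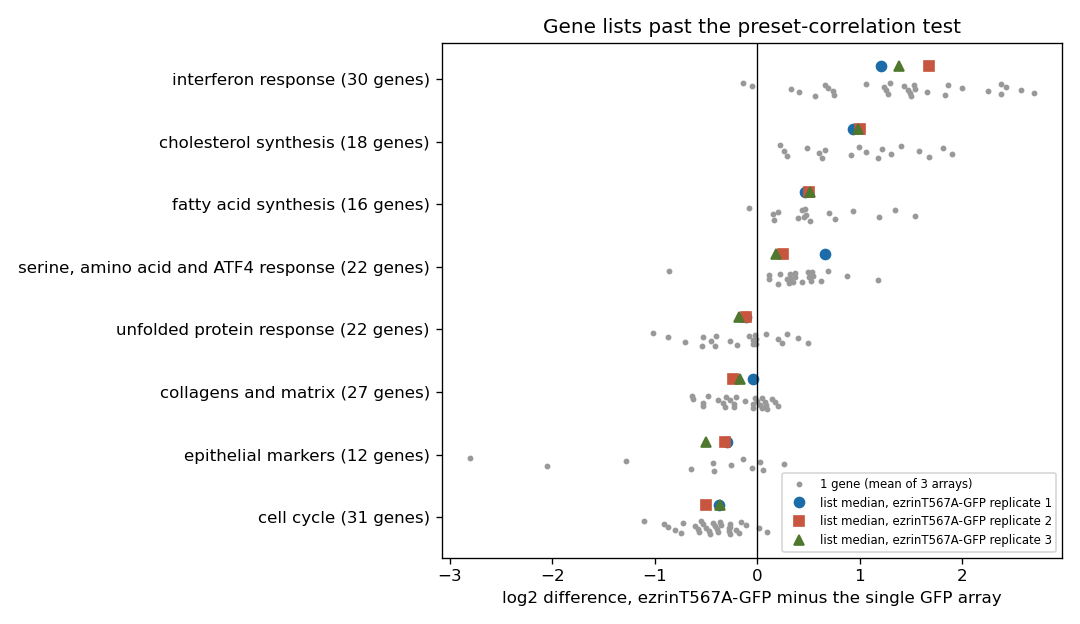
Log2 difference from the single GFP array (x axis) for the 8 lists past camera's threshold (y axis). Grey points are genes as means of 3 arrays and coloured markers are list medians per ezrinT567A-GFP array, which run from 1.21 to 1.67 for the interferon response and from -0.50 to -0.37 for the cell cycle.

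The series title names cellular metabolism, and the central carbon lists did not move as groups. Of 20 glycolysis and lactate genes 9 were higher and 11 lower (median -0.05, adjusted p = 0.612 with camera). Hexokinase Hk1 was 0.41 (SE 0.10) higher, Pfkp 0.39 (SE 0.15) higher, the pyruvate kinase gene Pkm lower by -0.25 (SE 0.09) and Pdk1, which restrains pyruvate oxidation, lower by -0.50 (SE 0.19, probe sets -1.11 to 0.25). Among 21 genes of the TCA cycle 13 were higher and 8 lower (median 0.03, adjusted p = 0.946), with citrate synthase Cs 0.51 (SE 0.15) higher and fumarase Fh1 (-0.49, SE 0.11), Suclg2 (-0.57, SE 0.16) and Sdha (-0.38, SE 0.11) lower. The TCA test pointed down with camera and up with fry although median and mean were above 0. Respiratory chain subunits split into 24 higher and 25 lower (median -0.0002, adjusted p = 0.923), with Ndufv2 (-0.33, SE 0.09), Ndufs1 (-0.33, SE 0.10) and Ndufa4 (-0.43, SE 0.13) lower and Atp5o (0.25, SE 0.08) higher. Fatty acid oxidation had 11 of 19 genes higher (median 0.08, adjusted p = 0.946), with the carnitine carrier Slc25a20 at 0.41 (SE 0.12) and the coactivator Ppargc1a at -0.56 (SE 0.16, probe sets -0.56 to 0.36). Adjusted over the list alone 0 genes passed in each of these 4 lists, as over all genes. In the mTOR list (median 0.08, adjusted p = 0.843, 0 of 22 genes adjusted over the list alone) the cap-binding Eif4e was lower by -0.53 (SE 0.08), the mTOR inhibitor Deptor by -0.84 (SE 0.19, probe sets -0.84 to -0.03), and Tsc1 was 0.45 (SE 0.13) higher.

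Ezrin's own family and its partners gave no group shift either (median 0.02 over 20 genes, adjusted p = 0.946, 0 adjusted over the list alone). The sister proteins moesin, Msn (-0.54, SE 0.20), and radixin, Rdx (-0.45, SE 0.17), were lower, the kinase Slk was 0.40 (SE 0.12) higher and Rhoa lower by -0.30 (SE 0.14). Probe sets disagreed for Slk (-0.09 to 0.40), which turned to -0.0325 with the _at kind alone, and for Rhoa (-0.30 to 0.03). Actin, SRF and YAP targets had a median of 0.12 (adjusted p = 0.439, 0 of 25 adjusted over the list alone), with the actin-binding Lima1 at 0.89 (SE 0.13, probe sets -0.10 to 0.89), vinculin, Vcl, at 0.50 (SE 0.14), Cnn2 at 0.42 (SE 0.15) and Ankrd1 at 0.85 (SE 0.30). Integrin and adhesion genes had a median of 0.02, a mean of -0.21 and a downward camera result (adjusted p = 0.382). Itga6 was the 1 gene that passed adjusted over the list alone, and the tetraspanin Cd9 (-0.49, SE 0.09), the neural adhesion molecule Ncam1 (-1.64, SE 0.35, probe sets -1.64 to 0.08) and the proteoglycan Gpc1 (-0.42, SE 0.12) were lower.

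Proteases and their inhibitors differed gene by gene rather than as a group (median -0.06, adjusted p = 0.448 with camera). Adjusted over the list alone 13 of 23 genes passed, 6 higher and 7 lower, and over all genes 0. Mmp13 and Adam12 were lower with the plasminogen activator inhibitor Serpinb2 (-1.72, SE 0.15), whose ezrinT567A-GFP level of 2.39 lay under the lower quartile of the arrays, and Adamts1 was higher.

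The hypoxia, NRF2, ribosome biogenesis and p53 lists stayed under the threshold. In the hypoxia list 13 of 20 genes were lower (median -0.13, adjusted p = 0.111, 0 adjusted over the list alone), with the prolyl hydroxylase Egln3 at -3.13 (SE 1.04), the carbonic anhydrase Car9 at -1.65 (SE 0.52), Bhlhe40 at -0.57 (SE 0.14) and Mxi1 at -0.35 (SE 0.13). With the mean of a gene's probe sets the hypoxia list passed (adjusted p = 0.00527), while the brightest probe sets gave adjusted p = 0.766 with an estimated correlation. In the NRF2 list 16 of 19 genes were higher (median 0.11, adjusted p = 0.111), and heme oxygenase, Hmox1 (0.86, SE 0.13), was the 1 gene that passed adjusted over the list alone, ahead of the pentose phosphate genes Tkt (0.43, SE 0.11), Pgd (0.59, SE 0.19) and Taldo1 (0.23, SE 0.08). The NRF2 list passed without replicate 2 (adjusted p = 0.0476) and with the spike-in covariate (median 0.51, adjusted p = 0.00115), while all 3 arrays without the covariate gave adjusted p = 0.888 with an estimated correlation. Ribosome biogenesis and MYC genes had a median of -0.03 (adjusted p = 0.327, 0 of 23 adjusted over the list alone), with Myc at -0.48 (SE 0.10), Dkc1 at -0.54 (SE 0.19) and nucleolin, Ncl, at -0.41 (SE 0.15). The p53 targets had a median of 0.08, a mean of -0.05 and a downward camera result (adjusted p = 0.946), and Perp was the 1 gene that passed adjusted over the list alone, while Trp53inp1 was 0.88 (SE 0.19, probe sets -0.06 to 0.88) higher and Phlda3 lower by -0.46 (SE 0.13).

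Chemokine, cytokine and NF-kB genes had a median of 0.04, a mean of -0.01 and adjusted p = 0.946, with 0 of 24 adjusted over the list alone. Cxcl12, a chemokine of stromal cells, was lower by -2.50 (SE 0.49, probe sets -2.89 to -0.31), Il11 by -0.45 (SE 0.11), while Ccl5, which is interferon-inducible, was 1.09 (SE 0.27) higher and the NF-kB inhibitor Tnfaip3 0.60 (SE 0.17) higher. Osteoblast genes had a median of 0.03, a mean of -0.08, and tests that pointed down with camera (adjusted p = 0.923) and up with fry. The phosphate-regulating Phex was lower by -1.10 (SE 0.50), Smad6 by -0.47 (SE 0.18), and the osteoblast transcription factor Sp7 was 0.26 (SE 0.14) higher, with 0 of 15 adjusted over the list alone.

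Markers of other cell types were mostly dim, with 5 of the 39 macrophage, endothelial and muscle markers above the median level of all genes. Macrophage and leukocyte markers had a median of 0.10 (adjusted p = 0.612), endothelial markers -0.05 (adjusted p = 0.612) and muscle markers 0.08 (adjusted p = 0.448). Chondrocyte and adipocyte markers had a median of -0.0004 and a mean of 0.002, with tests pointing down with camera (adjusted p = 0.946) and up with fry. The endotoxin coreceptor Cd14 (0.94, SE 0.13) was the 1 gene of these 4 lists that passed adjusted over the list alone. The pan-leukocyte gene Ptprc stayed near 2.22 in GFP and 2.11 ± 0.02 (SD, n = 3) in ezrinT567A-GFP, and Cldn5 (0.30, SE 0.14), Acta1 (0.27, SE 0.13) and Sox9 (-0.25, SE 0.18) showed similarly small differences.

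With an estimated correlation camera called 0 of the 27 lists, against 8 with the preset one, with 2 lists at an unadjusted p under 0.05. Fry called 1 list for movement on balance one way and 11 for movement in either direction. On data simulated for this comparison the estimated correlation called 0% of lists that had truly been shifted, so at this size its result carries little weight. The preset correlation called 20% of unchanged lists when their genes were correlated at 0.2. The estimated correlation was above 0.2 for the ATF4 (0.81), interferon (0.71), cell cycle (0.36) and epithelial (0.23) lists. It was below 0.2 for collagens (0.09), the unfolded protein response (0.08), fatty acid synthesis (0.03) and cholesterol synthesis (-0.06). False calls at correlations above 0.2 were not simulated.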

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

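The tests of the spike-in covariate, of replicate 2, of the single GFP culture, of the macrophage, endothelial and muscle markers and of other single-array groupings were chosen after the results they bear on had been seen, and the test of further keratinocyte genes was written before its values were seen but after the keratins had been.

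Some signals lay in probe sets that the comparisons did not use, above their level in the GFP array. The 18S rRNA probe sets of ezrinT567A-GFP replicate 2 were 2.26 above GFP on the log2 scale, while those of replicates 1 and 3 differed from GFP by -1.44 and -1.33. The hybridization spike-ins, added to the hybridization mix as a control, were 1.21 higher on average in the ezrinT567A-GFP arrays. Among 10092 probe sets without a single named gene, controls left out, 14 were at least 2-fold above GFP in all 3 ezrinT567A-GFP arrays and 10 were at least 2-fold below, next to 149 and 145 with a named gene. Groups of 3 arrays and of 1 array are too small to test an array for standing apart.

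The interferon-response genes were higher in all 3 ezrinT567A-GFP arrays, in step with the spike-ins. With the spike-in level as a covariate the list's median difference was 0.78 (quartiles 0.40 to 1.15), down from 1.45 but still past camera's threshold at the preset correlation. The covariate's slope came from the 3 ezrinT567A-GFP arrays alone, with spike-ins of 10.1, 11.1 and 10.4. It was extended to the GFP array at 9.32, outside their range. The covariate therefore cannot separate array brightness from the group. Brightness of a whole array would, however, also move other genes of similar level. Random lists matched on mean expression had medians from -0.11 to 0.15, tails left out, against 1.45 for this list. The median difference of all genes was 0.03. For the interferon list these values argue against brightness shared across an array as the cause. An effect limited to certain probe sets was not tested and stays open. Without the covariate the list's call was lost with fry (adjusted p = 0.201) and with an estimated correlation (adjusted p = 0.766). The latter called 0% of truly shifted lists in simulation, so that loss carries little weight. Without replicate 2 the median was 1.29, which argues against that array as the only source. The largest median difference between 2 ezrinT567A-GFP arrays was 0.44, which measures only the spread within that group, and because GFP has 1 array, an interferon response that was low in that culture cannot be told apart from an effect of ezrinT567A-GFP, which stays open and untested.

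Several keratinocyte genes were lower in the ezrinT567A-GFP arrays, led by Fabp5 (-3.77), Krt6a (-3.55), Krt14 (-2.80), Perp (-2.79), Krt17 (-2.54) and Dmkn (-2.50). The ezrinT567A-GFP levels of Perp (2.27), Dmkn (2.33), Krt17 (2.85) and Fabp5 (2.99) lay near or under the lower quartile of the arrays. The size and order of these differences are therefore uncertain. Keratinocyte RNA or cells in the GFP sample stays open: of 22 further keratinocyte genes 17 were lower, with a median of -0.3039 (quartiles -0.59 to -0.02) close to the bound of -0.3 set for it, but only 6 of the 22 lay above the median level of all genes, and 2 of these 6 were lower. Krt16 (-1.60) was the 1 of the 22 at least 2-fold lower, and Krt1, Krt10, Cdh3, Itgb4 and Dst were not lower, among them the 3 brightest in GFP, Dst (7.95), Itgb4 (7.63) and Krt10 (6.57). A lower share of osteosarcoma cells in the GFP sample stays open as well, since the lowest median of the macrophage, endothelial and muscle lists was -0.0463, but only 5 of their 39 genes lay above the median level of all genes, and markers of types not in a culture cannot move. Expression of keratins by the GFP-expressing K7M2 cells themselves stays open and was not tested, and 2 of the keratinocyte genes are also in the epithelial list.

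The number of genes at least 2-fold apart was 305 with GFP as the single array and at most 98 with another array as the single one. Of the 4 such groupings 1, the real one, gave as many, and 4 groupings are too few for a share under 0.05.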

How the results depend on the processing

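The spike-in covariate and the removal of tied genes were chosen after seeing the data. For every list the covariate reached outside the spike-in range of the ezrinT567A-GFP arrays, so calls kept, lost or gained with it decide little. For the count of genes past the threshold, 0 as reported, with or without the 2-fold minimum, quantile normalization gave 34 (17 higher, 17 lower), centring 30 (15 and 15), the mean of probe sets 6 (1 and 5), the filter on dim genes 3 (0 and 3) and the robust prior 9 (1 and 8), leaving out tied genes 28 (13 and 15), and a threshold of 0.1 gave 6. Leaving out 97 genes tied on all 3 arrays raised the prior degrees of freedom from 2.23 to 3.55, and quantile normalization and centring, which break the ties, to 3.84 and 3.66, so the ties account for much of the count of 0. Treat, eBayes without trend, the threshold of 0.01 and leaving out the _s_at, _x_at and _a_at kinds gave 0, and leaving out each replicate gave 0 to 0. The difference in Ezr was -0.0068 after centring and -0.0204 to 0.0615 without each replicate, all within its SE of 0.12, and 0.17 with the mean of probe sets and 0.33 with the _at kind alone, which exceed it without passing the threshold. The count of lists, 8, was 0 with an estimated correlation and 1 with fry, and 6 to 8 in all other settings, 6 to 7 without each replicate. The estimated correlation also called 0% of truly shifted lists in simulation, so its count of 0 carries little weight. The interferon, cholesterol, fatty acid, cell cycle, epithelial and ATF4 lists passed in all settings but the estimated correlation and fry (cholesterol passed with fry), except that the filter on dim genes left the epithelial list too short to test. Collagens were lost with the mean of probe sets, without replicate 2, without replicate 3 and with the spike-in covariate, where the median was -0.0023 and camera pointed up, and the unfolded protein response without dim genes, without trend, without each replicate and with the covariate; the cause was not tested. Hypoxia gained a call with the mean of probe sets, and NRF2 without replicate 2 and with the covariate. Lpl, 0.21 by its brightest probe set, turned to -0.13 with the mean of probe sets, which averages probe sets that disagree, and to -0.47 with the _at kind alone, as did Slk to -0.0325 and Sulf2 to 0.28, because another probe set then stands for the gene. Of 1301 alternative values of named genes other than Ezr 1219 kept direction and side of the threshold, 78 gained a call and 4 reversed. A robust prior was not run for lists, since camera does not take one. No paired analysis was possible because GFP has 1 array without a replicate number.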

Other observations

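The tests of chromosomes 1 and 16 were chosen after chromosome medians had been seen, and the genes named here were chosen after their values were seen, while the tests of the other Xist probe sets and of X-linked genes were set before their values were seen.

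Several of the largest differences in size lay outside the fixed lists. Map2 and Tubb3, cytoskeletal genes of neurons, were higher in ezrinT567A-GFP by 2.51 (SE 0.20) and 1.74 (SE 0.42), although other Map2 probe sets went down to 0.09 and the GFP level of 1.80 was near background. Aldh3a1, an aldehyde dehydrogenase, was higher by 2.29 (SE 0.29), from 5.38 in GFP to 7.67 ± 0.34 (SD, n = 3), Akr1c14, an aldo-keto reductase, from a GFP level of 2.51, also near background, to 4.51 ± 0.57 (SD, n = 3), and the tetraspanin gene Tspan6 by 2.63 (SE 0.27). None passed limma's test over all genes, with adjusted p from 0.153 (Map2) to 0.266 (Tubb3).

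Xist, the RNA that silences an X chromosome, was 9.33 in GFP and 7.30, 4.22 and 4.35 in ezrinT567A-GFP replicates 1, 2 and 3, with adjusted p = 0.338 in limma. All 3 Xist probe sets were lower, the smallest difference being -1.95, which argues against 1 faulty probe set. If the loss of Xist had released a silenced X, X-linked genes would be higher. Their median over 245 genes above the median level was -0.14, where random lists gave 0.04, so the X as a whole showed no rise. Whole autosomes had medians from -0.34 to 0.24, however, so a chromosome-wide shift of another origin, such as a lower dosage of the X, could hide a release. The values therefore cannot decide whether such a release took place.

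Whole chromosomes differed between the arrays, which is a hypothesis of unequal chromosome dosage found and tested on the same data. The values by chromosome cover only genes with a mean level above the median of all genes. Of 510 such chromosome 1 genes 83.7% were lower in ezrinT567A-GFP, and 100% of its windows of 25 such neighbouring genes had a median below -0.1, so the shift may reflect dosage of chromosome 1 along its whole length rather than a few gene clusters. Chromosome 1 was not alone in this: 65.8% of windows lay below -0.1 on chromosome 17, and 95.3% and 89.3% lay above 0.1 on chromosomes 8 and 18. The X-linked median lies inside the range of autosome medians (-0.34 to 0.24). Chromosome 16 separated the replicates: its median difference from GFP was -0.10 in replicate 1 against 0.26 and 0.33 in replicates 2 and 3, and 90.1% of its windows were below -0.1 in replicate 1 against the other 2, which is consistent with unequal dosage of chromosome 16 among the ezrinT567A-GFP arrays. Replicate 1 stood apart on other chromosomes as well. On chromosome 4 its median was 0.22, against -0.01 and 0.01 in replicates 2 and 3. On chromosome 15 it was 0.17, against -0.04 and 0.01, and on chromosome 18 it was 0.33, against 0.09 and 0.18. In the other direction, 52.0% of chromosome 12 windows were below -0.1 in replicate 1 against the other 2. DNA copy number was not analysed here, so no explanation other than gene clusters was excluded. Differences of single genes on these chromosomes could in part follow the chromosome.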
